A study of Mus musculus with 6 samples.

How the data were processed

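The series holds 6 RNA-seq libraries of mouse dorsal skin epidermis at postnatal day 2, 3 from suction blisters during healing and 3 from control skin. Per the labels, epidermal cells were freed with trypsin, RNA was taken up in TRIzol, messenger RNA was purified with oligo-dT beads and libraries were made with a TruSeq kit. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.0 and assigned to genes with featureCounts, whose version is not given in the sources used here, with NCBIM37 and mm9 named as builds. The values are raw read counts per gene as deposited by the authors, 1 table of gene symbols and whole numbers per library, with no scaling or filter applied before deposit that the values show. Of 24014 genes in each table, 3759 had no count in any library. The strand setting of the counting and the number of animals behind a library are not given in the sources used here.

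Total counts ran from 7600567 to 15912863 per library. TMM factors were 0.841, 0.957 and 0.953 for blister 1, 2 and 3 and 1.11, 1.06 and 1.11 for control 1, 2 and 3. All pairs of libraries within a group were compared gene by gene, and none was a copy of another. Of the symbols, 22709 matched the GENCODE M21 annotation and 22508 the RefSeq genes of GRCm38. No coordinates are given, since that annotation is on another build than the one the notes name, and genes are identified by symbol as the tables give it.

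Genes were tested with edgeR 4.0.16 (R 4.3.3), with quasi-likelihood fits and F-tests without robust estimation, TMM scaling and the group as the single term. Low counts were removed by filterByExpr by group (minimum count 10, minimum total count 15), which left 14028 genes. P-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. CPM values are counts scaled by library total and TMM factor, given as mean ± SD over 3 libraries, and SE is that of the log2 fold change, blister over control. Intervals and floors of counts, of 3 counts over a group where it had none, cover counting error only.

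Before the data were examined 30 gene lists were written from textbook markers, none chosen on these samples, together with the groups, tests, alternatives and rules for naming genes. The rules took the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM and groups that did not overlap, the 2 smallest p-values of each list of a biological programme, the most abundant tested member of each list of another cell type, and 9 markers regardless of outcome (Krt14, Krt10, Lor, Krt6a, Col17a1, Shh, Lef1, Sox9 and Mki67). This gave 64 genes, some of which are not reported here. Other genes in the text were chosen after their values were seen. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 30 lists, and beside it with an estimated correlation and with fry. Flg, Ly6g, Ahsp and Pi3 are not analysed here.

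The procedure was tested on simulated data of 13847 genes at these depths and this spread. At an adjusted p under 0.05 edgeR recovered 2 of 67 genes changed 1.5-fold, 28 of 67 changed 2-fold and 52 of 66 changed 4-fold, with 7 false calls (7.87% of calls), and camera found the 1 changed list of 30 genes at 2-fold and called 0 unchanged lists. Genes were drawn independently of each other, so this does not test camera's error where the genes of a list move together. Far fewer genes were changed than were called in the real data, so the recovery rates may not carry over.

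The alternatives set then were median-of-ratios, upper-quartile and library size scaling, no filter and a stricter filter (at least 5 CPM in 3 libraries), the replicate number as a block, leaving out the 50 most abundant genes, leaving out each library in turn, DESeq2 1.42.0, limma-voom, robust edgeR and a prior count of 0.5. Chosen after the data were seen were the log2 CPM of Xist and the mean level of dermal fibroblast markers as covariates, thinning to the smallest library, and leaving out blister 3 and control 3 together. Plots were drawn with matplotlib 3.10.9.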

Results

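RNA was sequenced from epidermal cells of newborn mouse back skin collected on postnatal day 2. In 3 libraries the skin had carried a suction blister, a separation of epidermis from dermis raised by negative pressure through a syringe, and was in the course of healing. The other 3 libraries came from control skin. Blisters were typically 3 mm across under a syringe 4 mm in diameter, and the suction was 523.4 ± 1.3 mmHg. The epidermis was detached with 0.25% trypsin, minced and passed through a 70 µm filter, so each library held whatever cells came away with the epidermis, hair follicles included. The files listed 24014 genes. The totals over genes were 12972196, 7600567 and 12367439 counts in blister libraries 1, 2 and 3, and 11743139, 13486784 and 15912863 counts in control libraries 1, 2 and 3. The labels do not say whether the libraries of a group came from separate animals. Sex-linked RNA, given below, shows that neither group came from a single animal. The p-values below measure the spread between these libraries, which may be partly technical.

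The comparison of blister with control asks how the epidermis of a healing blister differs from undisturbed epidermis of the same age, in a study concerned with hair follicle stem cell progeny and with skin development during repair. Stress keratins, small proline-rich genes, cytokines, chemokines and glycolytic genes rose in the blister libraries. Markers of the hair follicle, from the placode to the hair shaft, fell, and with them the targets of the Hedgehog and Wnt pathways. Dermal fibroblast markers fell as well (median log2 fold change -2.55). Whether less dermal tissue or fewer follicles were recovered, or genes fell within follicles, stays open. Krt6a, a keratin of wounded epidermis, averaged 5990.2 ± 222 CPM (counts scaled to library size with TMM factors) in blister libraries and 257 ± 109.8 CPM in controls (SD, n = 3 each), 23.4-fold higher. Shh, the Hedgehog ligand of the follicle, averaged 12.8 ± 1.03 against 39.4 ± 8.58 CPM, 3.08-fold lower. Of 14028 genes tested, 2993 (21.3%) differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1367 higher and 1626 lower in blister libraries. At least 2-fold changes were called for 438 genes that rose and 1063 that fell. Among the 30 gene lists, 20 passed limma's camera test with a preset inter-gene correlation of 0.01, 8 upwards and 12 downwards, while 0 passed once the correlation was estimated from the data and 13 passed the directional fry test. At an unadjusted p under 0.05, edgeR gave 5477 genes.

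**Figure D1:**
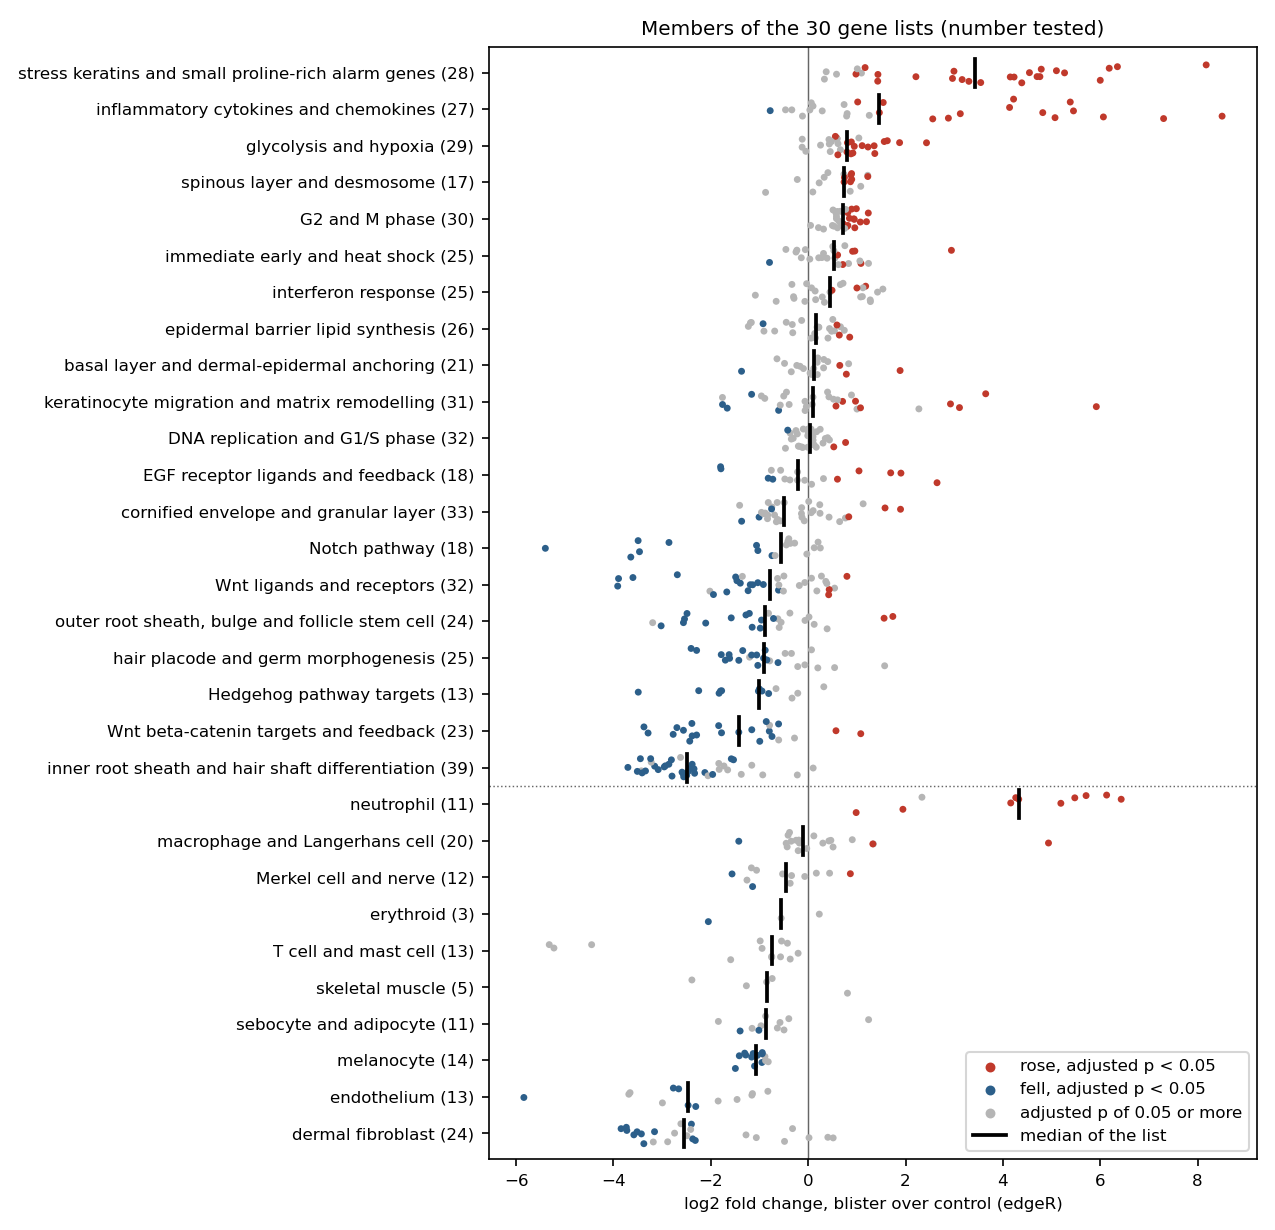
Log2 fold change of blister over control from edgeR (horizontal axis) for each tested member of 30 gene lists, with the number tested after each list's name and a black bar at the list's median; red points rose and blue points fell at an adjusted p under 0.05, and lists under the dotted line are markers of other cell types. The medians run from 4.33 for neutrophil markers and 3.42 for stress keratins and small proline-rich genes down to -2.50 for inner root sheath and hair shaft genes and -2.55 for dermal fibroblast markers.

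The libraries of a group resembled each other more than those of the other group, with one blister library in between. Pearson's r of log2 CPM across genes, which are not independent replicates, lay between 0.957 and 0.975 within blister, between 0.967 and 0.988 within control and between 0.883 and 0.957 across groups. The first principal component held 67.7% of the variance and placed blister 1 and 2 at 64.9 and 65.8, blister 3 at 23.1, and the controls at -45.6, -43.6 and -64.5. Libraries also differed in sex-linked RNA, and the groups were not balanced for it. Blister 1, blister 2 and control 1 were high in Xist, and blister 3, control 2 and control 3 in Ddx3y. Xist, which is transcribed from the inactive X chromosome, was at 838, 879 and 8.49 CPM in blister 1, 2 and 3 and at 1409, 16.9 and 0.512 CPM in control 1, 2 and 3, and Ddx3y, on the Y chromosome, was at 0.275, 0.826 and 62.0 CPM and at 1.30, 40.2 and 60.3 CPM in the same order. With log2 CPM of Xist as a covariate, an alternative chosen after the data were seen, edgeR called 1696 genes. The 50 most abundant genes held 27.9%, 20.8% and 21.7% of counts in blister libraries against 15.6%, 18.1% and 14.95% in controls.

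The basal layer list did not pass its test, while its most abundant keratins rose. Krt14, which with Krt5 forms the filaments of basal keratinocytes, rose from 7739 ± 265 to 28645 ± 6513 CPM (SD, n = 3), a log2 fold change of 1.89 ± 0.20 (SE) with an edgeR adjusted p of 0.00449, and Krt5 rose by 0.78 ± 0.16 on the same scale (edgeR adjusted p = 0.0188). Reads of Krt14 may be shared with its close relatives Krt16 and Krt17, so its value carries that uncertainty. Col17a1, a hemidesmosome collagen that anchors basal cells to the dermis, stood at 2082 ± 198 against 1672 ± 174 CPM (log2 fold change 0.32 ± 0.14, edgeR adjusted p = 0.147). Of 21 tested members of the basal and anchoring list, 3 rose and 1 fell, the same numbers adjusted over the list alone. The camera adjusted p was 0.292, and 0.0208 without blister 1. The integrin gene Itga6 rose too, from 336 to 528 CPM (edgeR adjusted p = 0.0352, or 0.126 without control 1), and the keratin gene Krt15 was at 1479 against 2307 CPM (edgeR adjusted p = 0.0695). The member that fell was Lama5, a laminin chain of basement membranes (232 against 599.9 CPM). The Krt5 call was lost when control 1, 2 or 3 was left out, with an edgeR adjusted p of up to 0.0867 without control 1.

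Spinous genes rose in part. Of 17 tested members of the spinous and desmosome list 7 rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 fold change of 0.74 and a camera adjusted p of 0.0016 (adjusted p = 0.558 with an estimated correlation). The desmosomal plaque gene Dsp rose from 3362 to 6247 CPM and Krtdap from 1232 ± 209 to 2263 ± 427 CPM. Krt10, the suprabasal keratin, varied as much within groups as between them, at 59274, 18622 and 32104 CPM in blister libraries and 17598, 31198 and 17318 CPM in controls (log2 fold change 0.73 ± 0.43 (SE), edgeR adjusted p = 0.239). The list's median was 0.48 without blister 1, and its camera adjusted p became 0.0863 without the 50 most abundant genes, 0.12 without blister 3 and control 3, and 0.822, with a median of 0.31, with the level of dermal fibroblast markers as a covariate (the dermal covariate, chosen after the data were seen), and the edgeR call of Krtdap was lost in 4 of the 6 fits that left out 1 library, reaching 0.0695 without blister 1.

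Cornified envelope and granular layer genes went both ways. Lor, the main protein of the cornified envelope, fell from 3463 ± 962 to 1720.3 ± 502 CPM, a log2 fold change of -1.01 ± 0.28 (SE, edgeR adjusted p = 0.0418). Rptn rose from 58.2 ± 26.0 to 217 ± 104 CPM and Lce3c from 4.52 ± 0.981 to 13.6 ± 4.86 CPM. Among 33 tested members 3 rose and 3 fell, as they did adjusted over the list alone, with a median of -0.49 and a camera adjusted p of 0.292. The list passed downwards without blister 3 (camera adjusted p = 0.00703) and its test turned upwards without blister 2 (0.923). The Lce genes lie in a family of similar sequences, and reads may be split among them. In the list for synthesis of barrier lipids, 3 of 26 tested members rose and 1 fell, again the same adjusted over the list alone, with a median of 0.17, a mean of -0.02 and a camera adjusted p of 0.528, upwards. It passed without blister 2 (camera adjusted p = 0.0435) and turned downwards without blister 1 (0.967) and without control 3 (0.903). Cers3, a ceramide synthase, rose from 56.6 ± 5.59 to 102 ± 29.2 CPM, and the lipoxygenase gene Aloxe3 fell from 79.1 ± 8.81 to 41.4 ± 11.8 CPM. The edgeR calls of Lor, Rptn, Lce3c, Cers3 and Aloxe3 were each lost in 2 to 4 of the 6 fits that left out 1 library, with adjusted p of up to 0.121, 0.0696, 0.0627, 0.0989 and 0.0749.

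Stress keratins and alarm genes rose as a group. Of 28 tested members 23 rose and 0 fell (26 and 0 adjusted over the list alone), with a median log2 fold change of 3.42, which stayed at 3.42 with Defb4 set at the bound its absent control counts allow, and a camera adjusted p of 2.42e-17 (adjusted p = 0.389 with an estimated correlation). Krt6b and Krt16, keratins induced in wounds, rose from 78.4 to 5019 CPM (3115 without blister 1) and from 337 to 7056 CPM. Sprr2h, a cornified envelope precursor, rose from 15.1 ± 3.59 to 120.1 ± 23.8 CPM (log2 fold change 2.99 ± 0.22 (SE), edgeR adjusted p = 0.00343), and Sprr1b from 73.0 to 654 CPM. The alarmin genes S100a8 and S100a9 reached 162 and 250.2 CPM from 2.22 and 3.08 CPM. Defb4, an antimicrobial peptide gene, had 84 counts in the blister libraries and 0 in the controls, at least 42.0-fold higher against a floor of 3 counts over the control group, with counting error only. Markers of neutrophils, which also make S100a8 and S100a9, rose with this list (median 4.33). Krt17 was at 4219.9 against 2819.5 CPM (edgeR adjusted p = 0.0526). Krt6a and Krt6b, the Sprr2 genes and the Stfa genes are near-identical copies whose reads may be split or shared.

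**Figure D2:**
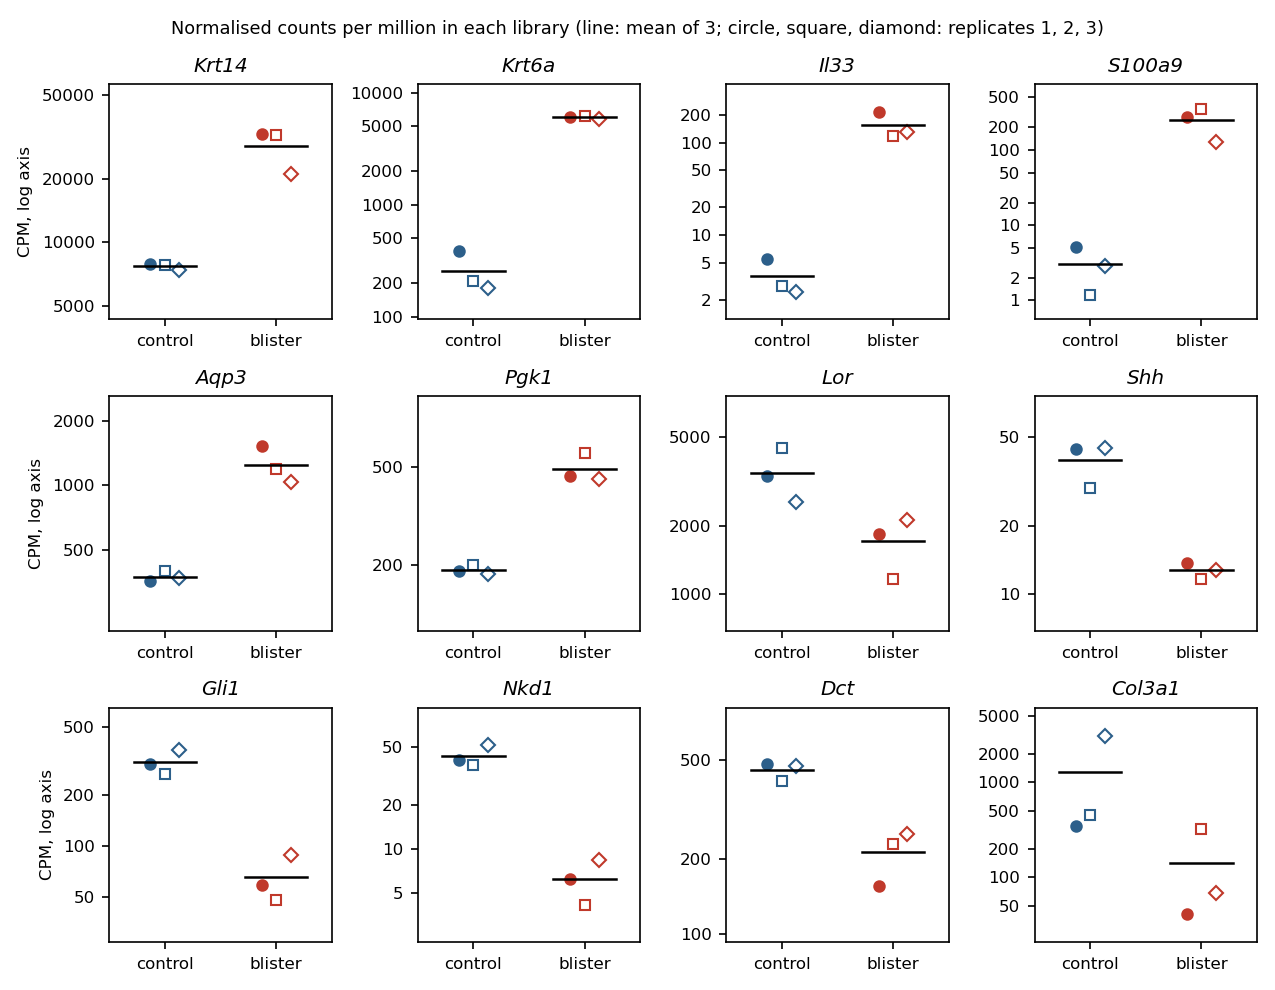
Normalised CPM on log axes for 12 genes in the 3 control libraries (blue) and the 3 blister libraries (red), with the mean of each group as a line. Circles, squares and diamonds are replicates 1, 2 and 3, which are not known to be paired between groups. Krt6a lies at 5744 CPM or above in each blister library and at 382 CPM or below in each control, Shh at 13.8 CPM or below in blister and 29.5 CPM or above in control libraries, and Col3a1 is at 3089 CPM in control 3 against 344 and 449 CPM in the other controls.

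Inflammatory cytokines and chemokines rose together with markers of neutrophils. In the cytokine list 15 of 27 tested members rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 1.46 and a camera adjusted p of 9.55e-07 (adjusted p = 0.389 with an estimated correlation). Il33, an alarmin cytokine of barrier cells, rose from 3.56 ± 1.64 to 154 ± 51.6 CPM (log2 fold change 5.45 ± 0.38 (SE), edgeR adjusted p = 0.00343). The neutrophil attractant genes Cxcl2 and Cxcl3, whose sequences are similar, rose from 0.648 ± 0.634 to 98.4 ± 68.0 CPM and from 0.100 ± 0.118 to 36.5 ± 27.3 CPM. Their blister means were 64.5 and 22.45 CPM without blister 2, and their control means 0.282 and 0.035 CPM without control 1. Il1b rose from 1.64 to 66.5 CPM and Tslp, a keratinocyte cytokine, from 0.195 to 13.9 CPM, means that were 43.1 and 7.28 CPM without blister 1. The member that fell was Cxcl14 (497 to 289.6 CPM), a chemokine of resting epithelium. Among neutrophil markers 10 of 11 rose and 0 fell, as they did adjusted over the list alone, with a median of 4.33 and a camera adjusted p of 4.85e-08 (adjusted p = 0.389 with an estimated correlation). Csf3r, the receptor for granulocyte colony-stimulating factor, rose from 2.57 to 52.2 CPM. Il1r2, the decoy interleukin 1 receptor and the most abundant of these markers over the 6 libraries, rose from 23.1 ± 1.96 to 45.9 ± 13.7 CPM, a call lost in 5 of the 6 fits that left out 1 library (edgeR adjusted p up to 0.0829, without blister 1). The mean log2 CPM of the neutrophil list was 4.33, 4.66 and 2.97 in blister 1, 2 and 3 and -0.02, -0.32 and 0.74 in control 1, 2 and 3.

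Macrophage and Langerhans cell markers did not pass as a group. Of 20 tested members 2 rose and 1 fell (1 and 0 adjusted over the list alone), and the camera adjusted p was 0.776, with a median of -0.11, a mean of 0.30 and an upward test direction, which turned without blister 2 (0.603) and without control 2 (0.685). Cd14, a coreceptor for bacterial lipopolysaccharide that neutrophils and keratinocytes can also make, rose from 3.54 ± 1.98 to 108 ± 54.3 CPM (log2 fold change 4.94 ± 0.56 (SE), edgeR adjusted p = 0.00606). The other 2 calls were Tyrobp, which rose from 13.4 to 33.8 CPM, and Cx3cr1, which fell from 9.23 to 3.44 CPM. For T cell and mast cell markers 0 of 13 tested members passed, also adjusted over the list alone, although the list's median was -0.75 and its camera adjusted p 0.0145 (adjusted p = 0.389 with an estimated correlation). The median was -0.49 without control 1, and that adjusted p was 0.0781 with library size alone, 0.369 with a stricter filter and 0.0683 with the dermal covariate. Thy1, the most abundant of them, was at 33.6 ± 10.3 against 43.2 ± 6.62 CPM (edgeR adjusted p = 0.272).

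Genes of keratinocyte migration and matrix remodelling split in direction. Of 31 tested members 8 rose and 4 fell (11 and 7 adjusted over the list alone), and the camera adjusted p was 0.388 with a median of 0.10. The collagenase gene Mmp13 rose from 3.36 to 42.0 CPM and Mmp9, a gelatinase that neutrophils also carry, from 0.873 to 52.0 CPM, means that rested on blister 2 and were 16.4 and 16.6 CPM without it. Plaur, the urokinase receptor gene, rose from 3.81 ± 1.27 to 29.3 ± 16.7 CPM and Tgfbi, a matrix protein gene, from 307 ± 9.26 to 601 ± 77.1 CPM (log2 fold change 0.97 ± 0.14 (SE), edgeR adjusted p = 0.00769). Fn1, the fibronectin gene, fell from 298 CPM (178 without control 3) to 88.2 CPM. The EGF receptor list likewise held 5 members that rose and 4 that fell among 18 tested, the same adjusted over the list alone (limma camera adjusted p = 0.776, median -0.22, mean 0.02), and its test turned upwards without control 3 (0.964). Its risers included the ligand genes Epgn (8.56 ± 3.63 to 53.4 ± 15.04 CPM), Hbegf (15.5 ± 2.02 to 58.1 ± 21.7 CPM) and Areg (7.50 to 24.4 CPM). Spry4 and Dusp4, feedback inhibitors of the pathway, fell from 6.68 to 1.92 CPM and from 22.0 to 6.29 CPM (4.08 without blister 3).

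Immediate early, heat shock and interferon genes rose in smaller numbers. In the immediate early and heat shock list 6 of 25 tested members rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.53 and a camera adjusted p of 0.00556 (adjusted p = 0.523 with an estimated correlation). Fosl1, an AP-1 subunit gene, rose from 0.743 ± 0.352 to 5.96 ± 3.28 CPM and Klf6 from 93.9 ± 10.6 to 143 ± 13.3 CPM, while Fos stood at 336 against 199 CPM (edgeR adjusted p = 0.067). The edgeR calls of Fosl1 and Klf6 were lost in 2 and 3 of the 6 fits that left out 1 library, with adjusted p of up to 0.0567 and 0.0763 without control 1, and Klf6 also with library size alone (0.127). In the interferon list 3 of 25 tested members rose and 0 fell (1 and 0 adjusted over the list alone), with a median of 0.45 and a camera adjusted p of 0.0152 (adjusted p = 0.616 with an estimated correlation), which became 0.125 without blister 2 (median 0.19), 0.0752 without control 1 (median 0.21) and 0.0925 with a stricter filter. Irf9, a transcription factor gene of interferon signalling, was at 46.2 ± 4.72 against 32.9 ± 2.35 CPM (log2 fold change 0.49 ± 0.12 (SE), edgeR adjusted p = 0.0331), called in the full set of libraries but in 1 of the 6 fits with a library left out (edgeR adjusted p up to 0.132, without control 1).

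Glycolytic genes rose broadly. Of 29 tested members of the glycolysis and hypoxia list 17 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.80 and a camera adjusted p of 5.15e-09 (adjusted p = 0.389 with an estimated correlation). Slc16a3, a lactate exporter gene, rose from 10.5 ± 1.87 to 56.6 ± 15.5 CPM (log2 fold change 2.43 ± 0.23 (SE), edgeR adjusted p = 0.00418), and Pgk1, a glycolytic enzyme gene, from 192 ± 8.02 to 490.1 ± 67.8 CPM. The glucose transporter gene Slc2a1 rose from 168 to 496 CPM, Pkm from 538 to 1975 CPM and Ldha from 359 to 926 CPM. Hif1a, which encodes the oxygen-regulated subunit of hypoxia-inducible factor, rose from 80.5 to 189 CPM. Pseudogene copies of glycolytic enzymes may take part of their reads.

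Of the cell cycle lists 1 passed, and the difference between the lists was not tested. In the G2 and M phase list 14 of 30 tested members rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.72 and a camera adjusted p of 2.45e-07 (adjusted p = 0.523 with an estimated correlation). Its mean log2 CPM was 5.89, 6.65 and 6.42 in blister 1, 2 and 3. In control 1, 2 and 3 it was 5.35, 5.91 and 5.61, so the groups overlapped and the rise lay mostly in blister 2 and 3. Anln, needed for cytokinesis, rose from 52.8 ± 11.3 to 124 ± 35.7 CPM, Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, from 41.5 ± 7.64 to 95.4 ± 35.4 CPM, and Cdk1 from 71.8 to 133 CPM. Mki67, the usual proliferation marker, was at 503 ± 165 against 404 ± 66.5 CPM (log2 fold change 0.31 ± 0.26 (SE), edgeR adjusted p = 0.407). In blister 1 it was at 313 CPM, below each control. In the DNA replication and G1/S list 2 of 32 tested members rose and 1 fell, none of them adjusted over the list alone (0 and 0), with a median of 0.03 and a camera adjusted p of 0.776 whose direction turned without blister 2 (0.451). These were Ccne1, a cyclin gene (14.7 ± 1.75 to 25.1 ± 6.64 CPM), Rrm1, a ribonucleotide reductase gene, and E2f1 (36.5 ± 0.206 to 27.3 ± 2.34 CPM). The edgeR calls of Anln, Ube2c, Ccne1 and E2f1 were lost in 1, 2, 5 and 5 of the 6 fits that left out 1 library, with the highest adjusted p, 0.0603, 0.0782, 0.139 and 0.138, without control 1.

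Hair follicle genes fell across the lists fixed for them. For the inner root sheath and hair shaft, the innermost layers of a growing follicle, 26 of 39 tested members fell and 0 rose (32 and 0 adjusted over the list alone), with a median log2 fold change of -2.50 and a camera adjusted p of 2.87e-11 (adjusted p = 0.481 with an estimated correlation). Tchh, which hardens the inner root sheath, fell from 792 to 134 CPM and Krt71, an inner root sheath keratin, from 1015 to 99.7 CPM. Those blister means rested on blister 3, and without it were 76.5 CPM for Tchh and 23.8 CPM for Krt71. Krt35, a hair shaft keratin, fell from 184 to 13.6 CPM (1.54 without blister 3), Krt86, another, from 37.8 ± 8.502 to 12.6 ± 4.13 CPM, and the homeobox gene Msx2 from 35.1 ± 13.7 to 6.67 ± 2.63 CPM. For the outer root sheath, bulge and follicle stem cells 12 of 24 tested members fell and 2 rose (16 and 2 adjusted over the list alone), with a median of -0.89 and a camera adjusted p of 6.59e-04 (adjusted p = 0.459 with an estimated correlation). Sox11 fell from 11.5 ± 2.77 to 1.41 ± 0.190 CPM (log2 fold change -3.02 ± 0.28 (SE), edgeR adjusted p = 0.00418), Lhx2 from 192 to 44.4 CPM and Lgr5, a follicle stem cell receptor gene, from 43.0 to 7.04 CPM (2.11 without blister 3). Sox9, a transcription factor gene of the follicle lineage, fell from 94.5 ± 13.5 to 48.5 ± 15.4 CPM (edgeR adjusted p = 0.0279), a call lost in 4 of the 6 fits that left out 1 library, with up to 0.0935 without control 1. The members that rose were Aqp3, a glycerol and water channel gene also made by basal keratinocytes (374 ± 19.4 to 1249 ± 249.9 CPM), and Plet1 (42.4 to 125 CPM). In the placode and hair germ list 15 of 25 tested members fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.92 and a camera adjusted p of 4.12e-06 (adjusted p = 0.429 with an estimated correlation). Besides Shh (log2 fold change -1.62 ± 0.19 (SE), edgeR adjusted p = 0.00658), Pdgfa fell from 129.6 ± 9.09 to 68.6 ± 3.75 CPM and the ectodysplasin receptor gene Edar from 51.7 to 15.8 CPM.

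Pathway genes of follicle development fell alongside. Of 13 tested Hedgehog targets and components 9 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -1.003 and a camera adjusted p of 8.37e-05 (adjusted p = 0.481 with an estimated correlation). Gli1, a transcription factor gene that Hedgehog signalling induces, fell from 311 ± 52.4 CPM to 59.1, 47.9 and 88.6 CPM in blister 1, 2 and 3 (log2 fold change -2.25 ± 0.25 (SE), edgeR adjusted p = 0.00522). Among Wnt targets and feedback genes 18 of 23 fell and 2 rose (20 and 2 adjusted over the list alone), with a median of -1.43 and a camera adjusted p of 9.22e-08 (adjusted p = 0.389 with an estimated correlation). Nkd1, a feedback inhibitor, fell from 43.5 ± 7.29 to 6.26 ± 2.14 CPM (log2 fold change -2.77 ± 0.26 (SE), edgeR adjusted p = 0.00418), Lef1 from 48.5 ± 8.08 to 18.0 ± 2.61 CPM and Axin2 from 109 to 65.3 CPM. Myc and Cd44, both induced in wounds as well, rose from 104 to 221 CPM and from 421 to 625 CPM. Of 32 Wnt ligand and receptor genes 15 fell and 3 rose (19 and 3 adjusted over the list alone), with a median of -0.78 and a camera adjusted p of 0.00137 (adjusted p = 0.499 with an estimated correlation). Fzd2 fell from 79.1 ± 7.02 to 24.7 ± 6.95 CPM and Wnt6 from 82.1 ± 9.67 to 43.3 ± 1.38 CPM, whereas Wnt4 rose from 378 to 656 CPM, Fzd6 from 103 to 138 CPM and Wnt3 from 69.3 to 92.8 CPM. In the Notch list 8 of 18 tested members fell and 0 rose, as they did adjusted over the list alone, with a median of -0.56, or -0.36 without control 3, and a camera adjusted p of 3.53e-04 (adjusted p = 0.472 with an estimated correlation). Hes5, a Notch target gene, had 2 counts in blister libraries and 142 in controls, a rate 47.3 times higher in controls with an exact 95% counting interval of 12.9 to 395. Hey1 fell from 8.95 ± 2.67 to 0.669 ± 0.531 CPM (0.367 without blister 3), while the Notch target Hes1 stood at 83.0 against 72.0 CPM (edgeR adjusted p = 0.552).

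The fall of these follicle, Hedgehog, Wnt and Notch lists came with a difference in dermal RNA. Of 24 tested dermal fibroblast markers 11 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -2.55, or -1.18 without control 3, and a camera adjusted p of 2.03e-04 (adjusted p = 0.533 with an estimated correlation). Their mean log2 CPM was 2.87, 4.87 and 3.62 in blister 1, 2 and 3 and 5.06, 5.25 and 7.30 in control 1, 2 and 3. The most abundant, Col3a1, was at 143 ± 154 against 1294 ± 1555 CPM (edgeR adjusted p = 0.0726), with 3089 CPM in control 3, while Pdgfra fell from 38.6 CPM (23.3 without control 3) to 3.83 CPM and Col6a1 from 329 to 30.7 CPM. With the dermal covariate edgeR called 327 genes, and 23 of the 56 named genes past the threshold stayed past it. In that fit the log2 fold change was -1.55 for Shh (edgeR adjusted p = 0.0529), -1.46 for Lef1 (0.0502), -2.16 for Gli1 (0.0422) and -2.67 for Nkd1 (0.0267), and the inner root sheath and hair shaft list had a median of -3.49 (camera adjusted p = 4.31e-18). Without control 3 edgeR called 1315 genes.

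**Figure D3:**
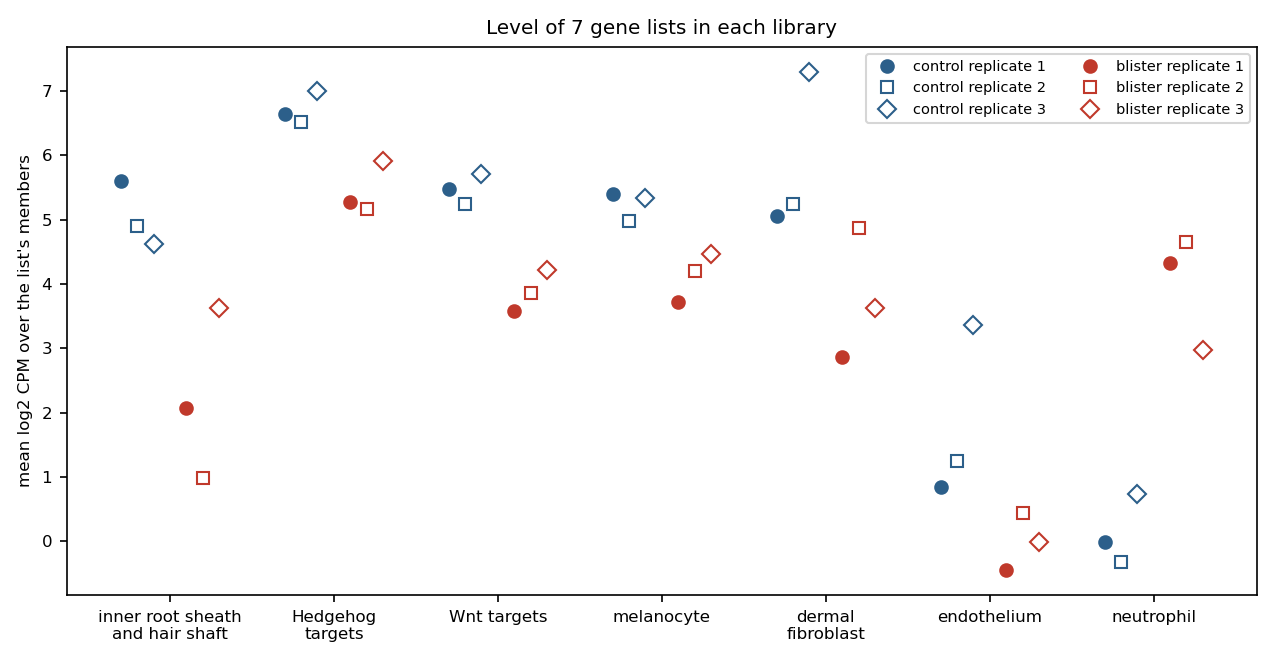
Mean log2 CPM over the members of 7 gene lists (vertical axis) in each of the 3 control libraries (blue) and 3 blister libraries (red); circles, squares and diamonds are replicates 1, 2 and 3. Inner root sheath and hair shaft, Hedgehog target, Wnt target and melanocyte lists lie lower in each blister library than in each control, neutrophil markers lie higher, and dermal fibroblast markers reach 7.30 in control 3.

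Markers of other cell types of the skin also differed. Of 14 tested melanocyte markers 11 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -1.07 and a camera adjusted p of 9.55e-07 (adjusted p = 0.481 with an estimated correlation). Dct, a pigment enzyme gene, fell from 457 ± 39.3 to 213 ± 50.3 CPM (log2 fold change -1.10 ± 0.19 (SE), edgeR adjusted p = 0.0128) and Sox10 from 43.6 to 19.5 CPM. Of 13 tested endothelial markers 5 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -2.47 and a camera adjusted p of 0.00145 (adjusted p = 0.524 with an estimated correlation). With the dermal covariate that list's median was -0.27 (camera adjusted p = 0.9). Eng, its most abundant gene, fell from 12.8 ± 6.11 to 2.60 ± 0.688 CPM. In the sebocyte and adipocyte list 2 of 11 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.0208, and adjusted p = 0.481 with an estimated correlation), Soat1 and Awat2, both of which esterify lipids. Its camera adjusted p was 0.164 without blister 1 (median -0.58), 0.0742 without control 2, 0.123 with library size alone and 0.0617 with the dermal covariate. Scd1, a fatty acid desaturase gene, stood at 363 ± 187 against 711 ± 330.0 CPM (edgeR adjusted p = 0.154). Merkel cell and nerve markers gave 1 that rose and 2 that fell among 12, the same adjusted over the list alone (limma camera adjusted p = 0.145). Mbp, known for myelin but also transcribed elsewhere, rose from 21.3 ± 1.22 to 39.0 ± 3.33 CPM, and Ncam1 and Piezo2 fell. Of 3 erythroid markers 1 fell, Slc4a1 (4.59 to 1.10 CPM), or 2 adjusted over the list alone, with a camera adjusted p of 0.125 that became 0.0213 without blister 2. Bpgm was at 21.1 ± 5.65 against 30.8 ± 3.49 CPM (edgeR adjusted p = 0.0868). Skeletal muscle markers gave 0 calls among 5, also adjusted over the list alone (limma camera adjusted p = 0.776, turning upwards without control 3 at 0.41), and Mylpf was at 6.55 ± 1.37 against 10.9 ± 7.59 CPM, the latter resting on 19.6 CPM in control 3.

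The largest changes were taken among genes of at least 5 CPM on average with groups that did not overlap. Next to Cxcl3, Cxcl2 and S100a9, the top risers were Osm, a cytokine gene of myeloid cells (0.208 ± 0.160 to 21.1 ± 9.12 CPM, 99.2-fold), and Irg1, which makes itaconate in activated myeloid cells. Irg1 had 302 counts in blister libraries and 2 in controls, a rate 226.5 times higher with an exact 95% counting interval of 62.2 to 1878. The top fallers were Sox18, a transcription factor gene of vessels and of the dermal papilla (66.5 ± 9.24 to 2.10 ± 3.40 CPM), the leptin receptor gene Lepr (16.7 ± 3.78 to 0.685 ± 0.511 CPM), Sparcl1 (71.8 ± 37.4 to 3.18 ± 3.32 CPM), Abca8a (13.9 ± 19.5 to 0.652 ± 0.514 CPM) and Mfap4 (25.4 ± 33.9 to 1.42 ± 1.41 CPM). The blister means of Sox18, Lepr and Sparcl1 rested on blister 3 and were 0.138, 0.390 and 1.33 CPM without it, and the log2 fold change of Sox18 was then -8.57, against -4.28 without blister 1. The control means of Abca8a and Mfap4 rested on control 3, with 36.4 and 64.6 CPM. Without control 3 their log2 fold changes were -2.11 and -2.13, with the dermal covariate -0.25 (edgeR adjusted p = 0.823) and -0.33 (0.708), and their edgeR calls were lost in each of the 6 fits that left out 1 library.

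Groups did not overlap at 6254 genes (44.6% of those tested), where chance gives 10%. Of the 56 genes past the threshold among the 64 named by rule, 37 stayed past it in each of the 6 fits that left out 1 library. The number of genes called by edgeR ranged over those fits from 785 without control 1 to 4061 without blister 3, and was 1028 without blister 1 and 1299 without control 2. Scaling moved the balance of calls, since 45.7% of called genes rose with TMM scaling, 34.4% with upper-quartile scaling and 16.1% with library size alone, which shifted the median log2 fold change of all genes to -0.253. In simulated data of the same depth edgeR recovered 2.99%, 41.8% and 78.8% of genes changed 1.5-fold, 2-fold and 4-fold.

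Genes named above outside that rule were chosen after their values were seen. The edgeR calls of Wnt4, Myc, Spry4 and Sox10 were lost without control 1, with adjusted p of 0.0595, 0.0549, 0.0547 and 0.0507. Those of Cxcl14 were lost in 2 of the 6 fits that left out 1 library, those of Itga6, Tchh, Fn1, Mmp13 and Cd44 in 3, those of Dusp4, Cdk1, Soat1 and Awat2 in 4, and those of Lama5, Dsp, Areg, Krt35, Krt71, Lgr5, Wnt3, Fzd6, Axin2, Rrm1, Tyrobp, Cx3cr1 and Piezo2 in 5, with an edgeR adjusted p of up to 0.159 for Wnt3 without control 1.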

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

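The direction of all 2993 called genes held under every alternative that tested them, while the number of calls varied. The Xist and dermal covariates, thinning and leaving out blister 3 with control 3 were chosen after the data were seen. Genes called ranged from 785 to 4061 with each library left out, and numbered 1696 with Xist and 327 with the dermal level as a covariate. The genes rising in blister numbered 544 with library size alone, 306 to 1998 over left-out libraries, 680 with Xist and 220 with the dermal level, and genes falling in blister 2831, 479 to 2063, 1016 and 107. For 2-fold changes the calls were 676 to 1850 over left-out libraries and 321 with the dermal level. The genes rising at least 2-fold numbered 286 with the stricter filter, 246 to 551 over left-out libraries and 218 with the dermal level, and genes falling at least 2-fold 1613 with library size alone, 375 to 1299 over left-out libraries and 103 with the dermal level. Library size alone leaves out the TMM factors, which were 0.841 to 0.957 in blister libraries and 1.06 to 1.11 in controls. These fits cannot tell a difference in composition from a net shift of expression. For the other counts the cause was not tested. DESeq2 called 3948 genes, 2924 of them shared. With the replicate number as a replicate block edgeR called 2876 genes, 2440 of them shared, no list changed its call and 7 named genes lost theirs. The labels do not say whether the numbers pair the libraries. Deviations from the group mean correlated at 0.21, -0.26 and 0.01 between libraries 1, 2 and 3 of the groups, which shows no shared pattern but cannot exclude a pairing.

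Of the 30 lists, 20 passed, 0 with an estimated correlation and 13 with fry, and 19 to 21 over left-out libraries. Adjusted p with an estimated correlation was 0.389 for stress keratins, Wnt targets, cytokines, glycolysis, neutrophils and T and mast cells, 0.429 for placode, 0.459 for outer root sheath, 0.472 for Notch, 0.481 for inner root sheath, Hedgehog, melanocytes and sebocytes, 0.499 for Wnt ligands, 0.523 for G2 and M phase and immediate early genes, 0.524 for endothelium, 0.533 for fibroblasts, 0.558 for spinous and 0.616 for interferon. With fry it was 0.0503 for inner root sheath, 0.127 for G2 and M phase, 0.181 for immediate early, 0.182 for spinous, 0.306 for interferon, 0.173 for fibroblasts and endothelium, 0.0865 for sebocytes and 0.0268 for erythroid markers.

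With the dermal level as a covariate camera gave 0.00182 for basal, 0.822 for spinous, 0.00891 for cornified, 0.000672 for migration, 0.0683 for T and mast cells, 0.973 for fibroblasts, 0.9 for endothelium and 0.0617 for sebocytes, and opposite directions for barrier lipids (0.0131), EGF receptor genes (0.798) and muscle (0.0154). With library size alone it gave 0.0478 for migration, 0.0781 for T and mast cells and 0.123 for sebocytes, and opposite directions for EGF receptor genes (0.663), DNA replication (0.762) and muscle (0.75). The stricter filter gave 0.0925 for interferon and 0.369 for T and mast cells, and opposite directions for DNA replication (0.968) and macrophages (0.932). With Xist as a covariate EGF receptor genes (0.996), macrophages (0.917) and muscle (0.968) turned, and thinning turned muscle (0.877). Without blister 3 and control 3 together, camera gave 0.12 for spinous and 0.00501 for cornified, and barrier lipids (0.467) and muscle (0.159) turned. Spinous reached 0.0863 without the 50 most abundant genes. Over left-out libraries adjusted p ranged from 0.0208 to 0.608 for basal, 0.00703 to 0.923 for cornified, 0.0435 to 0.967 for barrier lipids, 0.675 to 0.964 for EGF receptor genes, 0.179 to 0.962 for DNA replication, 0.000847 to 0.125 for interferon, 0.264 to 0.914 for macrophages, 0.318 to 0.95 for muscle, 0.0213 to 0.29 for erythroid and 0.00313 to 0.164 for sebocytes. Apart from the fibroblast list, which the dermal covariate removes by construction, the cause was not tested.

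Of the 56 named genes past the threshold, 33 were not past it with the dermal covariate, 12 with Xist, 5 without blister 3 and control 3, 3 with library size alone, and 2 each with upper-quartile scaling, voom and robust edgeR. Among the others, log2 fold changes that turned were those of Thy1 (0.033 with the dermal covariate), Krt10 (-0.33 with it) and Mylpf (0.45 with it, -1.02 to 0.009 over left-out libraries, the latter without control 3, and 0.18 without blister 3 and control 3), and the cause was not tested. Col3a1 passed with DESeq2 (adjusted p = 0.0397) and without blister 2 (0.049), Bpgm with library size alone (0.0395) and without blister 2 (0.0306), and Scd1 without blister 3 and control 3 (0.019). At the smallest library's depth edgeR called 2781 genes, 2602 of them shared.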

Other observations

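Genes outside the 30 lists also differed, and those named in this paragraph were chosen after their values were seen. Crabp2, which binds retinoic acid (81.4 ± 21.9 to 267 ± 9.80 CPM, SD, n = 3), and Aldh1a3, which makes it (7.35 ± 3.32 to 55.2 ± 23.9 CPM), rose with edgeR adjusted p of 0.00658 and 0.00812. The kallikrein proteases Klk6 and Klk10 rose from 48.8 to 331 CPM and from 85.3 to 365 CPM, and Serpinb2, an inhibitor of urokinase, from 66.0 ± 9.14 to 387 ± 96.7 CPM. Il4ra, a receptor subunit for interleukins of type 2 immunity, rose from 20.4 to 102 CPM. H19, an imprinted noncoding RNA, rose from 1569 ± 482 to 4862 ± 690.2 CPM (log2 fold change 1.63, edgeR adjusted p = 0.00865), while Igf2, its neighbour, was at 471 ± 95.6 against 345 ± 258 CPM (edgeR adjusted p = 0.513). In each of these called genes the 3 blister values lay above the 3 control values. Gsta4, Srxn1 and Slc7a11, genes of the antioxidant response, rose from 2.79 ± 0.749 to 53.8 ± 10.8 CPM, from 18.2 ± 1.45 to 63.6 ± 9.88 CPM and from 5.31 ± 1.21 to 24.1 ± 8.75 CPM. A wider rise of targets of the transcription factor NRF2 was put as a hypothesis and tested on 25 other targets listed before their values were seen. Of these 5 rose and 3 fell, with a median log2 fold change of 0.29 and a fry p of 0.191, so the test did not show a shift of the targets as a set. Those that rose were Txn1, Cbr3, Prdx1, Pgd and G6pdx (0.955, 0.928, 0.818, 0.686 and 0.517). Those that fell were Ephx1, Gclc and Txnrd1 (-0.888, -0.80 and -0.67).

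The tests in the paragraphs that follow were chosen after the patterns were seen, except that of dermal papilla genes, whose list and bound were written before its result. Intervals given there with medians and with differences of medians come from a bootstrap over genes, not over libraries. They treat genes measured in the same 6 libraries as independent and leave out the spread between libraries. They are too narrow as a measure of that spread, and none of them decides a cause alone. There are 10 ways to split the 6 libraries into groups of 3, too few for a share under 0.05. The real split called 2993 genes and 1501 with at least a 2-fold change, against at most 1 in any other split for either count, so 1 of the 10 splits reached each. For lists passing camera the real split gave 20 and the highest other 22, with blister 1, blister 2 and control 3 together, so 2 of the 10 splits reached as many. The lowest other split still passed 12 lists, so the number of lists passing with the preset correlation does not set the real grouping apart.

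The fall of the follicle, Hedgehog and Wnt lists came with less dermal RNA in blister libraries, and over 148 members of the 6 lists the median log2 fold change was -1.31 (95% bootstrap interval -1.64 to -1.03), -1.21 (-1.52 to -0.94) without control 3, where dermal markers still had -1.18 (-2.14 to -0.02), and -1.15 (-1.55 to -0.81) with the dermal level as a covariate, where the dermal markers went from -2.55 to 0.15 (-0.96 to 0.74). The fit with the covariate, not that without control 3, met the bound set against dermal fibroblasts as the whole cause, but it cannot exclude them. The covariate was the mean of these same dermal markers, so their move to 0.15 was fixed by construction. With so few libraries, an imperfect measure of dermal RNA could also leave part of such a fall. Calls of a fall went from 90 to 10 as the median SE widened from 0.27 to 0.40. The covariate shared variance with the group (R2 of 0.559), where Xist as a covariate (R2 of 0.12) left the SE at 0.27 and 75 calls. An equal loss of all follicle cells cannot be told apart from other losses, since inner root sheath keratins and hair shaft keratins differed by -0.95 (-1.55 to 0.12) on 9 and 18 genes. Pooled, these keratins fell further than melanocyte markers in these libraries, by a difference of -1.39 (-1.85 to -0.96, over genes only). Of 15 tested dermal papilla genes 12 fell, with a median of -3.01 and a limma fry p of 0.00565 (camera p = 0.117 with an estimated correlation). Of the 15, 7 were in the fixed lists too, so their values were not new to this test. In control 3 the 14 papilla genes outside the fibroblast list exceeded the other controls by 0.52, where fibroblast markers did by 1.73. This difference of -1.21 (-2.39 to -0.71) could come from papilla cells recovered with follicles more than with loose dermis, though it rests on 1 library. Whether fewer follicles were recovered from blistered skin, or their genes fell within follicles, stays open, and repair itself, the biological difference the design names, is untested as a cause.

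The rise of stress keratins and small proline-rich genes came with neutrophil transcripts, and without 8 genes that neutrophils also make 16 of 20 tested members rose, with a median of 3.42. Divided after the joint ratio was seen, the summed gain of Krt6a, Krt6b, Krt16 and Krt17 was 37.8, 15.6 and 44.4 times that of neutrophil markers with S100a8, S100a9, Slpi and Lcn2 in blister 1, 2 and 3. The keratins' gain was thus far above that of these genes. The sum covers chosen neutrophil genes and not all neutrophil RNA, so these ratios alone do not settle the source of the keratins' rise. With Stfa genes and Cd24a counted as neutrophil transcripts too, the keratins' gain was 4.9, 5.7 and 7.7 times the neutrophil gain. These ratios stayed above the neutrophil gain but under the 10 first set for excluding neutrophils. That bound was later set aside, because Stfa3 stood at 1180.2 CPM in controls, where Csf3r was at 2.57 CPM. For 11 small proline-rich genes the ratios to neutrophil markers with S100a8, S100a9, Slpi and Lcn2 were 1.97, 1.06 and 2.66. These ratios compare amounts of RNA and cannot tell epidermal from neutrophil sources. In controls Sprr1a and Sprr1b already stood at 246 and 73.0 CPM, while Sprr2f and Sprr2k were at 0.0613 and 0.0701 CPM. For the other 5 members (Defb4, Defb14, Gjb2, Gjb6 and Serpinb3a) the ratios to the same neutrophil genes were 0.82, 0.15 and 0.66. Neutrophil RNA would give ratios this low, but so would small gains from any source, so they decide nothing. Gjb2, Serpinb3a and Gjb6 already stood at 206, 69.9 and 39.0 CPM in controls. For S100a8 and S100a9 the ratio to Csf3r varied up to 1.9-fold among blister libraries (3.86 to 7.34 for S100a9 and 2.24 to 3.95 for S100a8), so the 2 sources cannot be told apart for them either. No gate removed blood cells, and wounding as the biological cause is left untested.

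Blister 3 lay between the other blister libraries and the controls. If control-like tissue were mixed in, genes that rose and genes that fell should give the same share, and they gave 46.4% from 530 genes and 24.8% from 1273 genes, a difference of 21.6 points (18.9 to 25.7). The same difference was 19.8 points for blister 1 and -1.6 for blister 2, neither of which lies between, so the size of the difference does not separate mixing from ordinary spread, and mixing cannot be told apart from slower or later healing, which was not tested. Blister 3 also differed from blister 1 and 2 in sex-linked RNA, with Xist at 8.49 CPM against 838 and 879 CPM. Control 2 and 3 were low too (16.9 and 0.512 CPM), and the part this difference plays was not tested.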
